A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

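The series holds 12 RNA sequencing libraries of Saccharomyces cerevisiae BY4741, 3 at each of 0, 1, 3 and 6 h in concanamycin A at 500 nM. Per the labels' protocols, cells were broken with beads, RNA was purified on RNeasy columns and treated with DNase, rRNA was removed with Ribo-Zero Gold and stranded total RNA libraries were prepared with TruSeq reagents. Because total RNA was sequenced without selection for poly(A), non-coding RNAs take part of the counts, and the share of each kind of RNA affects the scaling of the rest. Groups and hours came from the labels. The labels do not say that the libraries of a time came from separate cultures, so p-values then measure only the spread between these samples, which may be technical.

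The deposited table holds raw counts per feature, whole numbers that the authors made from aligned reads. The submitters' processing notes name STAR 2.5.2b, featureCounts 1.5.1 and the genome build R64. The annotation release, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Reads of near-identical copies could therefore be split or dropped, and overlapping genes on opposite strands could share reads, so such genes are named as uncertain. The table had 6216 features and 3 blank lines, which were left out. By kind these were 5771 nuclear open reading frames, 299 tRNAs, 82 snoRNAs or snRNAs, 28 mitochondrial open reading frames, 16 rRNAs, 16 other non-coding RNAs and 4 reading frames of the 2-micron plasmid. A symbol stood beside 5103 features, and 5808 matched a locus tag of the reference annotation, which is the same build. As 2 symbols had turned into dates, features were joined by systematic identifier. Coordinates are those of the reference annotation, counted from 1, and cover the whole gene.

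Library totals ran from 8508894 to 11008709 counts, and 135 features were at 0 in every library. All pairs of libraries of a time differed by more than sampling noise (chi-square per degree of freedom 3.25 to 31.9, the highest values, 31.9 and 22.4, with 0 h replicate 3), so no library was counted as a copy of another. Totals differed by less than 1.5-fold, and the spread between libraries of a time exceeded the counting error.

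The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood (robust fits, 8 residual degrees of freedom), after edgeR's filter on low counts, which kept 5615 features and left 601 untested, and TMM scaling. TMM factors were 0.843 to 0.881 at 0 h, 0.995 to 1.01 at 1 h, 1.07 to 1.11 at 3 h and 1.03 to 1.09 at 6 h. All 12 libraries entered the fit, so the 4 times shared an estimate of the spread (common dispersion 0.00753, a biological coefficient of variation of 8.68%). The 5 comparisons were 1, 3 and 6 h against 0 h, 3 h against 1 h and 6 h against 3 h, and an F test covered the 4 times. p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. A standard error is the absolute log2 fold change divided by the square root of F. CPM values are counts scaled to a common library size, computed by edgeR from TMM-adjusted totals.

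For named genes the rule took, in each comparison with 0 h, the 12 largest increases and 8 largest decreases among features past the threshold with a mean of at least 10 CPM in the higher group and all 3 libraries of a time on the same side of all 3 at 0 h. It took 5 per direction in the other comparisons, up to 4 members of each gene list with the largest change past the threshold, and the deletion markers of the strain. The text prints part of these. Gene lists, 33 in number, were written before the data were examined, and all their symbols were found. Limma 3.58.1 tested 32 of them with camera on log2 CPM with a prior count of 2, against the other features, at a preset correlation of 0.01, and again with a correlation estimated from the libraries, with fry as a further alternative. A list needed 4 tested members. The counts of members adjusted over the list alone use p-values adjusted within the list. Near-identical copies were found with blastn 2.17.0 (at least 95% identity over at least 50% of the length).

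The steps were tested on simulated data with 200 of 5615 genes changed in each comparison, in both directions and with independent noise in each library. These data therefore test neither TMM scaling where many more features change, as here, nor deviations shared between libraries. For 1 h against 0 h, 82.1%, 94.0% and 98.5% of the genes changed by 1.5, 2 and 4-fold were recovered, and 4.69% of calls were false. These values were 76.1%, 98.5%, 95.5% and 4.76% for 3 h against 0 h, 83.6%, 91.0%, 93.9% and 7.73% for 6 h against 0 h, 76.1%, 95.5%, 100% and 3.72% for 3 h against 1 h, and 86.6%, 89.6%, 98.5% and 4.69% for 6 h against 3 h. The simulated data and the random groupings of the 12 libraries were each drawn 2 times, because the digits of the first seeds clashed with printed values in a check of the texts. The second draws are reported as they came, and in the first draws, too, the real grouping called the most genes.

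The alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, total counts alone, no filter, a filter at 10 CPM in 3 libraries, features without rRNA, a fit of only the groups compared, a prior count of 0.5 and each library left out in turn. Alternatives added after seeing the data were a block on the replicate letter of the column headers, nuclear open reading frames only, all comparisons without 0 h replicate 3, and the estimated correlation of lists without each library.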

Results

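RNA sequencing followed transcript levels in Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a, during exposure to concanamycin A. This macrolide inhibits the vacuolar proton pump (V-ATPase), which acidifies the vacuole. Cultures in rich medium (YPD) were kept in the exponential phase and exposed to the compound at 500 nM during 0, 1, 3 or 6 h, with 3 libraries at each time. The 3 comparisons with 0 h addressed which transcripts differed after each exposure. The comparisons of 3 h with 1 h and of 6 h with 3 h addressed which differed between consecutive times. Libraries from cultures kept for 1, 3 or 6 h without the compound were not analysed here, so time in culture and exposure changed together in every comparison.

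The libraries of replicates 1, 2 and 3 held 11008709, 9041041 and 8844437 counts at 0 h, 9505589, 10232571 and 10479391 at 1 h, 8580004, 8686849 and 10195012 at 3 h, and 9644204, 9061684 and 8508894 at 6 h. Of 6216 features, 5615 were tested. Nuclear open reading frames took 81.6% to 85.5% of counts in the 6 h libraries and 87.7% to 91.2% in the others. The share of SCR1, the RNA of the signal recognition particle, was 6.95% ± 0.751 (SD, n = 3) at 6 h, against 4.92% ± 0.523 at 0 h. BY4741 carries deletions in LEU2, URA3, MET17 and HIS3. Over the 12 libraries together LEU2 had 8 counts, URA3 had 20 and MET17 had 0, while HIS3 had 363 to 860 counts per library. The strain lacks only part of HIS3, and whether these counts come from the remaining part was not tested.

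The first principal component held 51.8% of the variance and ordered the libraries by time, and the second held 23.1%. Replicate 3 at 0 h lay at 6.07 on the second component, away from replicates 1 and 2 at 17.8 and 16.7. In that library 172 features differed by more than 2-fold from the mean of the other 2 at 0 h (24 higher, 148 lower). The same count was 69 and 34 for replicates 1 and 2 at 0 h, whose comparison includes replicate 3, and 5 to 23 for the libraries at later times. Its environmental stress response genes had a median log2 difference of -1.08, its glucose-repressed genes -0.74, its autophagy genes -0.47, its vacuolar hydrolases -0.32, its ribosome biogenesis genes 0.23 and its ribosomal protein genes 0.18.

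**Figure D1:**
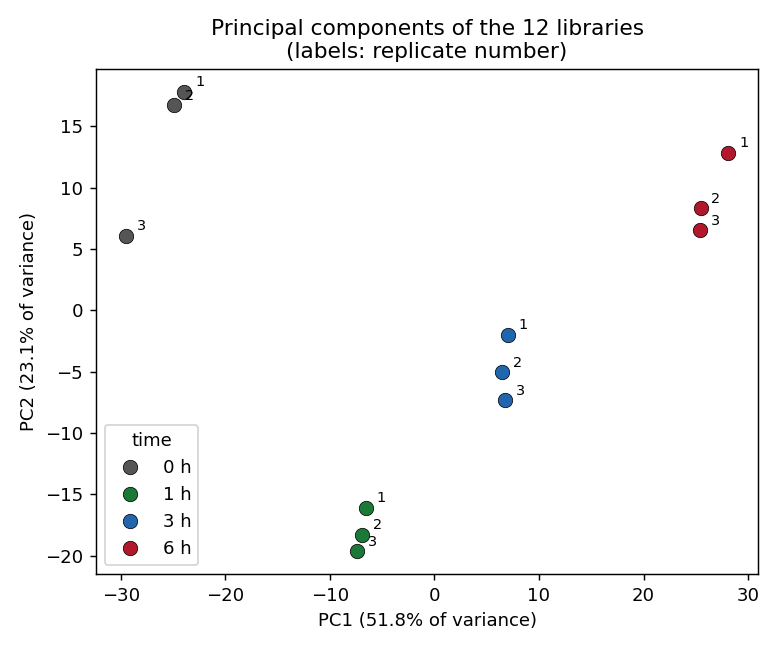
Principal components of the 12 libraries from log2 CPM, with the first component (51.8% of the variance) on the horizontal axis and the second (23.1%) on the vertical axis. Each point is a library, its colour is the time in 500 nM concanamycin A and its number is the replicate; 0 h replicate 3 lies at 6.07 on the second component, and 0 h replicates 1 and 2 lie at 17.8 and 16.7.

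Over the 4 times, 4406 of 5615 features (78.5%) changed by the edgeR F test at an adjusted p under 0.05. All fold changes below are relative to TMM scaling. With total counts alone, the median log2 fold change over all tested features was 0.21, 0.35 and 0.34 at 1, 3 and 6 h against 0 h, 0.13 at 3 h against 1 h and -0.02 at 6 h against 3 h. List medians printed without a value under total counts move by a similar amount. Small negative medians among them would therefore be closer to none under that scaling. "Rose" and "fell" describe features past the edgeR threshold. The p of a gene list is the camera p adjusted over 32 lists. For lists added after the results were seen, it is adjusted over only those added lists that camera could test. A p given with an estimated correlation is from the same test with the correlation among genes estimated from these libraries. A value beside a gene name is its log2 fold change, with its SE after ±.

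After 1 h, the phosphate uptake gene PHO84 stood far below its 0 h level, and SRX1 and GRE2 stood well above theirs. PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII, 24037 to 25800, minus strand), stood at 25.7 ± 0.651 CPM (normalised read count, mean ± SD, n = 3) against 1046 ± 212 at 0 h, a log2 fold change of -5.34 ± 0.18 (SE, adjusted p = 1.5e-09). SRX1, the sulfiredoxin that repairs peroxiredoxins (YKL086W, chromosome XI, 278281 to 278664, plus strand), stood at 51.7 ± 2.54 CPM against 5.39 ± 0.739, a log2 fold change of 3.25 ± 0.11 (adjusted p = 8.8e-11). GRE2, a methylglyoxal reductase (YOL151W, chromosome XV, 43694 to 44722, plus strand), reached 272 ± 26.6 CPM from 30.1 ± 1.92 (3.17 ± 0.08, adjusted p = 6.2e-12). Other large increases were in YNL134C (2.62 ± 0.09), the aromatic amino acid aminotransferase ARO9 (2.45 ± 0.07), the arginase CAR1 (2.43 ± 0.05), the phenylpyruvate decarboxylase ARO10 (2.27 ± 0.06) and the chaperone and glyoxalase HSP31 (2.06 ± 0.07). IRC15 (2.48 ± 0.16) overlaps CTF19 on the opposite strand by 27 bp, which leaves its value uncertain.

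In the phosphate regulon, the targets of Pho4, 15 of 18 genes fell and 0 rose at 1 h (16 fell adjusted over the list alone), with a median log2 fold change of -1.56 (adjusted p = 2.94e-11; adjusted p = 0.00195 with an estimated correlation). Besides PHO84, the sodium-phosphate transporter PHO89 (-4.74 ± 0.46), the inhibitor of phosphate transport SPL2 (-4.46 ± 0.16), the polyphosphate synthesis subunit VTC3 (-3.30 ± 0.06) and the acid phosphatase PHO5 (YBR093C, chromosome II, 429548 to 430951, minus strand, -3.14 ± 0.08) fell. PHO11 (-3.24 ± 0.17) and PHO12 (-3.84 ± 0.10) are near-identical copies that reads cannot always tell apart.

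Of 21 targets of Yap1, the regulator of the oxidative stress response, 17 rose and 0 fell at 1 h (17 and 1 adjusted over the list alone; median 0.77, adjusted p = 6.23e-09, adjusted p = 0.0489 with an estimated correlation). That call with an estimated correlation ended without single libraries, with an adjusted p of 0.0633 without 0 h replicate 1, 0.0590 without 0 h replicate 2, 0.066 without 1 h replicate 1 and 0.0621 without 1 h replicate 2. They included the thioredoxin TRX2 (1.59 ± 0.07) and the peroxiredoxin AHP1 (1.55 ± 0.05). The iron regulon, targets of Aft1 and Aft2, had 21 of 29 genes higher and 3 lower (21 and 3 adjusted over the list alone; median 0.69, adjusted p = 6.56e-07, adjusted p = 0.00524 with an estimated correlation). The siderophore transporter SIT1 (2.07 ± 0.17) and the heme oxygenase HMX1 (2.03 ± 0.21) were among them. Pleiotropic drug resistance genes rose in 8 of 13 cases, the same count adjusted over the list alone (median 0.73, adjusted p = 1.73e-04, but adjusted p = 0.0509 with an estimated correlation, and 0.0426 without 1 h replicate 1 or 0.0298 without 1 h replicate 3). The ABC transporter SNQ2 was at 1.10 ± 0.09. Heat shock proteins rose in 19 of 22 cases and fell in 2, also adjusted over the list alone (median 0.60, adjusted p = 9.06e-08, but adjusted p = 0.149 with an estimated correlation). HSP82, the inducible Hsp90, rose (1.76 ± 0.08), and BTN2, a protein-sorting factor, fell (-1.76 ± 0.23).

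Among ribosomal protein genes 134 of 138 fell and 0 rose at 1 h, the same counts adjusted over the list alone (median -0.99, adjusted p = 7.36e-50, but adjusted p = 0.148 with an estimated correlation). RPL7B, a large-subunit protein (YPL198W, chromosome XVI, 173152 to 174702, plus strand), went from 179 ± 0.893 to 27.8 ± 2.37 CPM (-2.69 ± 0.06). All 8 histone genes fell, also adjusted over the list alone (median -1.32, adjusted p = 3.42e-08, but adjusted p = 0.0629 with an estimated correlation). HTA2 was at -2.16 ± 0.07. Glycolysis genes fell in 14 of 17 cases (15 adjusted over the list alone; median -0.38, adjusted p = 5.0e-06, but adjusted p = 0.226 with an estimated correlation). In 0 h replicate 3 the ribosomal protein genes stood 0.18 above the other 2 libraries.

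Genes of iron-sulfur and heme proteins fell in 18 of 31 cases and rose in 4 (19 and 4 adjusted over the list alone; median -0.37, adjusted p = 3.06e-04, but adjusted p = 0.148 with an estimated correlation). LEU1, an iron-sulfur enzyme of leucine synthesis, fell (-2.13 ± 0.09) and the peroxisomal catalase CTA1 rose (1.69 ± 0.18). Heme synthesis genes fell in 6 of 8 cases and hypoxic genes in 9 of 20 with 2 higher, the same counts adjusted over the list alone (adjusted p = 0.0168 and 0.0468, but adjusted p = 0.149 and 0.148 with an estimated correlation), and both medians were negative at -0.34 and -0.37. The hypoxic call ended without 0 h replicate 1 (adjusted p = 0.0604) or 1 h replicate 3 (adjusted p = 0.0600), or with the filter at 10 CPM in 3 libraries (adjusted p = 0.0788). Sulfur amino acid genes controlled by Met4 rose in 15 of 28 cases and fell in 4 (16 and 4 adjusted over the list alone; median 0.33, adjusted p = 0.00936, but adjusted p = 0.239 with an estimated correlation). Autophagy genes rose in 13 of 27 cases, the same adjusted over the list alone (median 0.38, adjusted p = 0.00418, but adjusted p = 0.453 with an estimated correlation). The ER-phagy receptor ATG40 was at 1.45 ± 0.09. That list stood at a median of -0.47 from the other 2 libraries in 0 h replicate 3, without which 8 of 27 rose (median 0.20, adjusted p = 0.0329). Ribosome biogenesis genes fell in 22 of 50 cases and rose in 2 (23 and 2 adjusted over the list alone; median -0.18, 0.04 with total counts, adjusted p = 0.00372, but adjusted p = 0.653 with an estimated correlation). Their call ended without 0 h replicate 3 (adjusted p = 0.113), in which they stood 0.23 above. The a-specific mating genes rose in 5 of 7 cases (6 adjusted over the list alone; median 0.37, adjusted p = 0.0412, but adjusted p = 0.339 with an estimated correlation). In 0 h replicate 3 they stood a median of 0.38 above the other 2 libraries. That call ended without 0 h replicate 1 (adjusted p = 0.0580), 0 h replicate 2 (adjusted p = 0.0593) or 1 h replicate 3 (adjusted p = 0.0600).

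Subunits and assembly factors of the V-ATPase, the target of the compound, were not called at 1 h. Of 23 genes, 3 rose and 9 fell, the same counts adjusted over the list alone (median -0.09, 0.13 with total counts, adjusted p = 0.287), with VMA10 at 0.37 ± 0.06 and VMA1 at -0.31 ± 0.06. Without 0 h replicate 3, 1 rose and 9 fell (median -0.07, adjusted p = 0.364). The unfolded protein response list was not called either (8 of 16 higher, 2 lower, the same adjusted over the list alone; adjusted p = 0.234), although the ER chaperone KAR2 rose (1.03 ± 0.06). Zinc-responsive genes had a median of 0.04 and a mean of -0.20 (adjusted p = 0.389). The zinc transporter ZRT1 was at -2.57 ± 0.07. Environmental stress response genes were not called (8 higher and 4 lower of 30, 8 and 3 adjusted over the list alone, median -0.02, test direction up, adjusted p = 0.313), nor were glucose-repressed genes (0 higher and 6 lower of 22, 5 lower adjusted over the list alone, median -0.37, adjusted p = 0.125). Without 0 h replicate 3, in which these lists stood at -1.08 and -0.74, 8 stress response genes were higher and 14 lower (median -0.11, test direction down, adjusted p = 0.524). Without it the glucose-repressed list was called lower (13 genes lower, adjusted p = 0.0104, but adjusted p = 0.433 with an estimated correlation). So was the tricarboxylic acid cycle (12 lower, adjusted p = 0.0104, but adjusted p = 0.417 with an estimated correlation). Over all features at 1 h, 1375 rose and 1315 fell (141 and 182 by at least 2-fold), and 51.1% of calls were higher. With total counts 2575 were higher and 602 lower, 81.1% higher.

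**Figure D2:**
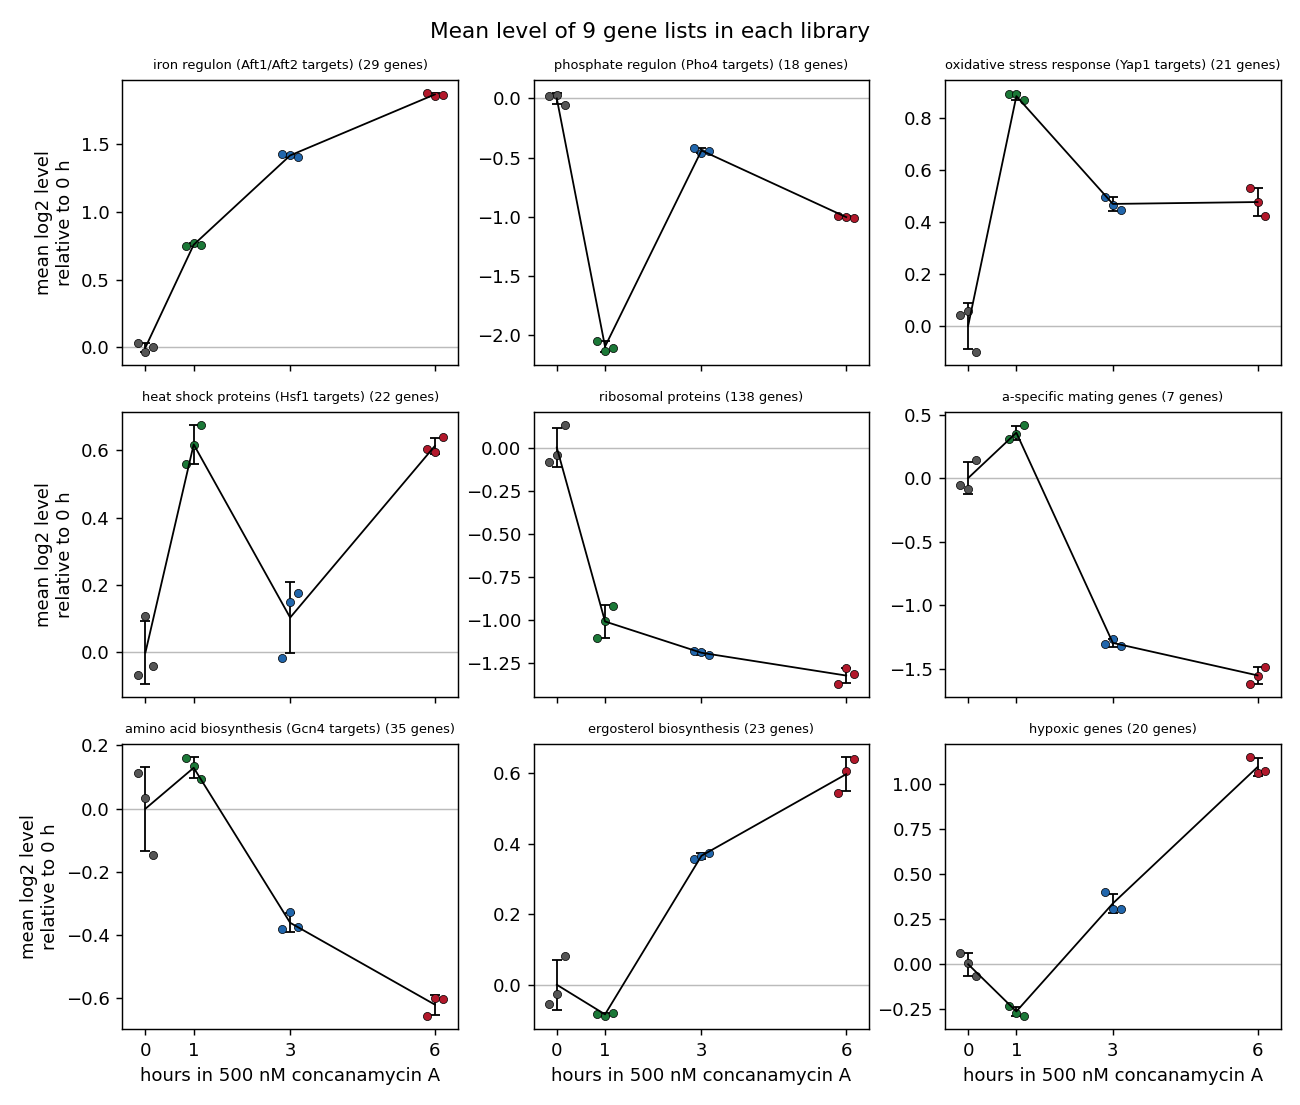
Mean log2 level of 9 gene lists relative to the 0 h mean, on the vertical axis, against hours in 500 nM concanamycin A on the horizontal axis. Each point is a library, and the line and bars are the mean ± SD of 3 libraries at each time; the mean of the phosphate regulon is -2.1 at 1 h, -0.44 at 3 h and -1.0 at 6 h, and that of the iron regulon is 0.76, 1.42 and 1.87.

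After 3 h, STR3 and MET2 of sulfur amino acid synthesis and FIT2 and FRE5 of iron uptake were higher than at 0 h, and the leucine synthesis gene LEU1 was lower. STR3, a cystathionine beta-lyase (YGL184C, chromosome VII, 154615 to 156012, minus strand), stood at 52.1 ± 7.11 CPM against 4.64 ± 0.546 (mean ± SD, n = 3), a log2 fold change of 3.47 ± 0.15 (SE, adjusted p = 8.3e-10). FIT2, a cell wall mannoprotein that retains siderophore iron (YOR382W, chromosome XV, 1059531 to 1059992, plus strand), reached 372 ± 14.8 CPM from 44.1 ± 0.983 (3.08 ± 0.06, adjusted p = 3.9e-12). LEU1 (YGL009C, chromosome VII, 476313 to 478652, minus strand) stood at 167 ± 14.2 CPM against 1571 ± 15.1, a log2 fold change of -3.23 ± 0.09 (adjusted p = 2.3e-11). HES1, an oxysterol-binding protein (YOR237W, chromosome XV, 781994 to 783298, plus strand), rose by 2.98 ± 0.12, the homoserine acetyltransferase MET2 by 3.20 ± 0.14 and the reductase homologue FRE5 by 3.13 ± 0.21. The glutamate synthase GLT1 (-2.52 ± 0.06), the purine synthesis enzyme ADE17 (-2.89 ± 0.26) and ZRT1 (-2.40 ± 0.07) fell. HO, the mating-type endonuclease gene, had a log2 fold change of -2.47 ± 0.45, and of -1.88 without 0 h replicate 3.

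The iron regulon had 26 of 29 genes higher and 0 lower at 3 h, the same adjusted over the list alone (median 1.18, adjusted p = 2.11e-14, adjusted p = 5.63e-04 with an estimated correlation). LSO1, a small protein of the iron response, rose (4.15 ± 0.38). Every other list called at 3 h lost its call with an estimated correlation, as each p below shows. Sulfur amino acid genes rose in 18 of 28 cases and fell in 2, also adjusted over the list alone (median 0.50, adjusted p = 4.55e-05, but adjusted p = 0.100 with an estimated correlation). Ergosterol synthesis genes rose in 15 of 23 cases with 0 lower, also adjusted over the list alone (median 0.23, adjusted p = 8.06e-05, but adjusted p = 0.217 with an estimated correlation). The sterol desaturase ERG3 was at 1.09 ± 0.06. Yap1 targets rose in 11 of 21 cases and fell in 1 (11 and 2 adjusted over the list alone; median 0.27, adjusted p = 9.57e-04, but adjusted p = 0.188 with an estimated correlation), with SRX1 at 2.14 and the cytochrome c peroxidase CCP1 at -0.98. Autophagy genes rose in 11 of 27 cases and fell in 1 (10 and 1 adjusted over the list alone; median 0.20, adjusted p = 0.0134, but adjusted p = 0.435 with an estimated correlation). That call ended without 0 h replicate 3 (7 higher and 1 lower, median 0.02, adjusted p = 0.148), in which the list stood at -0.47, and without 0 h replicate 2 also 7 rose.

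Ribosomal protein genes fell in 134 of 138 cases and rose in 2 at 3 h, also adjusted over the list alone (median -1.21, adjusted p = 1.6e-54, but adjusted p = 0.128 with an estimated correlation). In glycolysis 16 of 17 genes fell, also adjusted over the list alone (median -0.60, adjusted p = 8.37e-09, but adjusted p = 0.136 with an estimated correlation). Targets of Gcn4, the activator of amino acid synthesis, fell in 24 of 35 cases and rose in 5, also adjusted over the list alone (median -0.26, 0.07 with total counts, adjusted p = 1.92e-04, but adjusted p = 0.262 with an estimated correlation), with HIS1, the first enzyme of histidine synthesis, at -1.33 ± 0.06. All 7 a-specific genes and all 8 histone genes fell, also adjusted over the list alone (medians -1.33 and -0.92, adjusted p = 3.48e-05 and 2.37e-06, but adjusted p = 0.100 for both with an estimated correlation). Tricarboxylic acid cycle genes fell in 12 of 16 cases and retrograde response genes in 7 of 9 with 0 higher, also adjusted over the list alone (medians -0.40 and -0.45, adjusted p = 1.32e-04 and 0.00168, but adjusted p = 0.220 and 0.100 with an estimated correlation), with the aconitase ACO1, a member of both, at -2.26 ± 0.07. The cycle genes stood at -0.24 in 0 h replicate 3.

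The V-ATPase list was called lower at 3 h, with 12 of 23 genes lower and 2 higher, also adjusted over the list alone (median -0.23, 0.10 with total counts, adjusted p = 0.0212, but adjusted p = 0.196 with an estimated correlation). Its assembly factor VOA1 fell (-0.53 ± 0.09). Oxidative phosphorylation genes fell in 18 of 36 cases and rose in 2, also adjusted over the list alone (median -0.21, 0.12 with total counts, adjusted p = 0.00158, but adjusted p = 0.369 with an estimated correlation). The cytochrome c isoform CYC1 was at -1.31 ± 0.11. Iron-sulfur and heme protein genes fell in 17 of 31 cases and rose in 6 (17 and 7 adjusted over the list alone; median -0.40, adjusted p = 0.00910, but adjusted p = 0.220 with an estimated correlation). Phosphate genes fell in 10 of 18 cases and rose in 4, also adjusted over the list alone (median -0.58, adjusted p = 0.00910, but adjusted p = 0.100 with an estimated correlation). Over all features at 3 h, 1474 rose and 1377 fell (152 and 251 by at least 2-fold), and 51.7% of calls were higher. With total counts 3576 were higher and 498 lower, 87.8% higher.

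**Figure D3:**
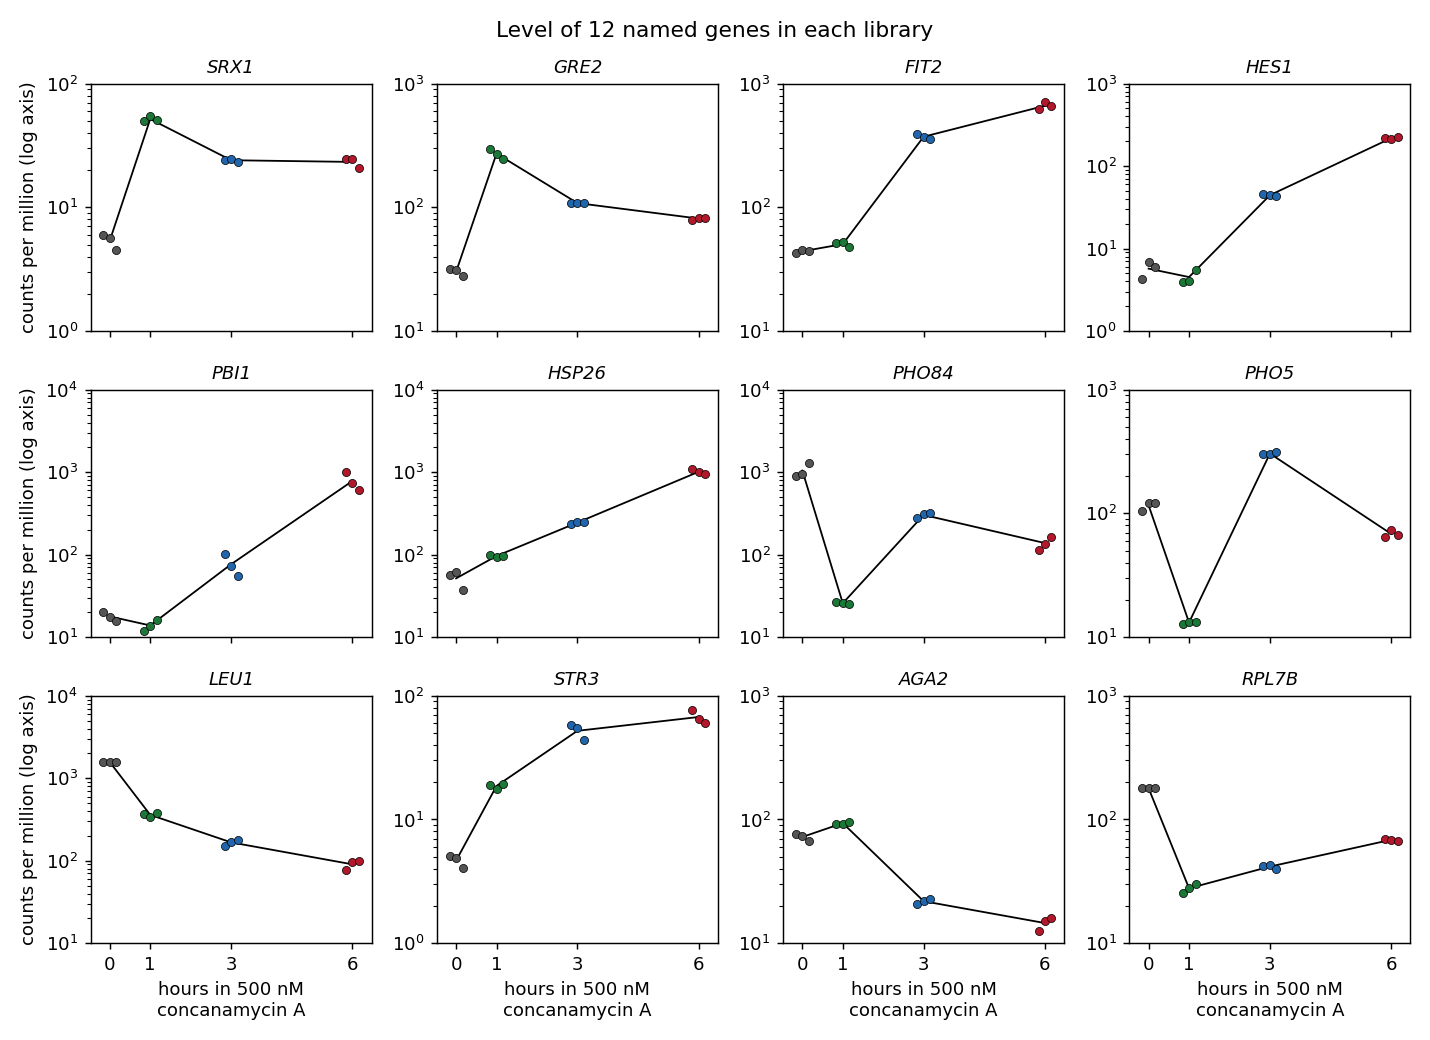
Level of 12 named genes in CPM, on a log axis, against hours in 500 nM concanamycin A. Each point is a library and the line joins the means of 3 libraries at each time; PHO84 goes from a mean of 1046 at 0 h to 25.7 at 1 h and 303 at 3 h, and PBI1 goes from 17.8 at 0 h to 782 at 6 h.

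After 6 h, PBI1, HES1, DAN1 and the small heat shock protein gene HSP26 were higher than at 0 h, and LEU1 and ILV3 of branched-chain amino acid synthesis were lower. PBI1 (YPL272C, chromosome XVI, 26611 to 28164, minus strand) stood at 782 ± 196 CPM against 17.8 ± 2.16 (mean ± SD, n = 3), a log2 fold change of 5.45 ± 0.28 (SE, adjusted p = 5.0e-08). HES1 reached 219 ± 5.63 CPM (5.28 ± 0.12) and DAN1, a cell wall mannoprotein of anaerobic growth, 84.2 ± 1.62 CPM against 3.84 ± 0.826 (4.45 ± 0.13). HSP26 (YBR072W, chromosome II, 382030 to 382674, plus strand) stood at 1011 ± 69.6 CPM against 51.5 ± 12.6 (4.29 ± 0.15). LEU1 stood at 90.4 ± 11.4 CPM against 1571 ± 15.1 (-4.12 ± 0.09, adjusted p = 1.5e-12) and ILV3, a dihydroxyacid dehydratase of the same pathway, at 229 ± 41.8 against 1790 ± 16.2 (-2.97 ± 0.11). The SET-domain protein gene SET4 (4.93 ± 0.15), FIT1 (4.04 ± 0.12), the hexose transporter HXT5 (3.97 ± 0.25) and STR3 (3.85 ± 0.15) rose. GLT1 (-3.17 ± 0.07), PHO84 (-2.92 ± 0.16) and CYC1 (-2.80 ± 0.13) fell.

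The iron regulon had 28 of 29 genes higher and 0 lower at 6 h, also adjusted over the list alone (median 1.15, adjusted p = 4.78e-13, adjusted p = 8.17e-04 with an estimated correlation). The phosphate regulon was lower, with 12 of 18 genes lower and 3 higher (13 and 3 adjusted over the list alone; median -0.95, adjusted p = 1.52e-04, adjusted p = 0.0365 with an estimated correlation). The call with an estimated correlation ended without 0 h replicate 1 (adjusted p = 0.0542), 0 h replicate 2 (adjusted p = 0.0719) or 0 h replicate 3 (adjusted p = 0.0922). The other lists called at 6 h lost their calls with an estimated correlation. Hypoxic genes rose in 14 of 20 cases and fell in 3, also adjusted over the list alone (median 0.94, adjusted p = 9.70e-04, but adjusted p = 0.0523 with an estimated correlation). The cell wall mannoprotein TIR1 was at 3.45. Ergosterol synthesis genes rose in 17 of 23 cases and fell in 1, and sulfur amino acid genes rose in 20 of 28 cases and fell in 5, also adjusted over the list alone (medians 0.49 and 0.71, adjusted p = 1.72e-05 and 7.24e-04, but adjusted p = 0.166 and 0.130 with an estimated correlation). Nitrogen catabolite repressed genes rose in 13 of 26 cases and fell in 4, also adjusted over the list alone (median 0.37, adjusted p = 0.0194, but adjusted p = 0.130 with an estimated correlation). The proline oxidase PUT1 was at 1.92 ± 0.13. Yap1 targets rose in 13 of 21 cases and fell in 4, also adjusted over the list alone (median 0.33, adjusted p = 0.0186, but adjusted p = 0.288 with an estimated correlation).

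Heat shock proteins rose in 13 of 22 cases and fell in 7 at 6 h (14 and 7 adjusted over the list alone; median 0.66, adjusted p = 0.0440, but adjusted p = 0.539 with an estimated correlation), with the Hsp70 genes SSA3 at 3.43 ± 0.07 and SSA4 at 2.96 ± 0.13. This call ended without 0 h replicate 1 (adjusted p = 0.0624) or 6 h replicate 3 (adjusted p = 0.0577). It also ended with a block on the replicate letter of the column headers (adjusted p = 0.0508). Environmental stress response genes rose in 16 of 30 cases and fell in 2, also adjusted over the list alone (median 0.69, adjusted p = 0.00309, but adjusted p = 0.576 with an estimated correlation). They stood at -1.08 in 0 h replicate 3, and without it 16 rose, 7 fell and the median was 0.32 (adjusted p = 0.0184). Autophagy genes rose in 22 of 27 cases and vacuolar hydrolases in 10 of 13 with 2 lower, also adjusted over the list alone (medians 0.60 and 0.56, adjusted p = 1.34e-04 and 0.0239, but adjusted p = 0.261 and 0.504 with an estimated correlation). The vacuolar protease PRB1 was at 1.91 ± 0.09. The hydrolase call ended without 6 h replicate 1 (adjusted p = 0.0613). These lists stood at -0.47 and -0.32 in 0 h replicate 3, without which 16 autophagy genes rose and 1 fell.

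Ribosomal protein genes fell in 135 of 138 cases and rose in 2 at 6 h, also adjusted over the list alone (median -1.34, adjusted p = 3.05e-43, but adjusted p = 0.130 with an estimated correlation). Ribosome biogenesis genes fell in 31 of 50 cases, also adjusted over the list alone (median -0.29, 0.02 with total counts, adjusted p = 8.70e-06, but adjusted p = 0.504 with an estimated correlation), and stood 0.23 above in 0 h replicate 3. Gcn4 targets fell in 25 of 35 cases and rose in 4 (25 and 5 adjusted over the list alone; median -0.64, adjusted p = 2.47e-06, but adjusted p = 0.166 with an estimated correlation). Glycolysis genes fell in 15 of 17 cases and all 8 histone and 7 a-specific genes fell, also adjusted over the list alone (medians -0.81, -1.40 and -1.65, adjusted p = 5.92e-08, 2.47e-06 and 1.28e-04, but adjusted p = 0.130, 0.121 and 0.121 with an estimated correlation).

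V-ATPase genes fell in 16 of 23 cases and rose in 2 at 6 h (17 and 2 adjusted over the list alone; median -0.42, adjusted p = 2.27e-04, but adjusted p = 0.0909 with an estimated correlation). The membrane subunit VMA16 was at -0.88 ± 0.06. Iron-sulfur and heme protein genes fell in 20 of 31 cases and rose in 5 (20 and 6 adjusted over the list alone; median -0.71, adjusted p = 5.39e-04, but adjusted p = 0.130 with an estimated correlation). Oxidative phosphorylation genes fell in 19 of 36 cases and rose in 2, also adjusted over the list alone (median -0.25, 0.05 with total counts, adjusted p = 0.00309, but adjusted p = 0.478 with an estimated correlation). The tricarboxylic acid cycle was not called (adjusted p = 0.109) except without 0 h replicate 3 (3 higher and 11 lower, adjusted p = 0.0336, but adjusted p = 0.526 with an estimated correlation). Over all features at 6 h, 1855 rose and 1620 fell (361 and 292 by at least 2-fold), and 53.4% of calls were higher. With total counts 3278 were higher and 809 lower, 80.2% higher.

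The fold changes at different times against 0 h were compared across genes, which are not independent replicates. The Pearson correlation was 0.732 between 1 h and 3 h, 0.821 between 3 h and 6 h and 0.582 between 1 h and 6 h (Spearman 0.693, 0.768 and 0.582). Comparisons with the same 0 h libraries share their chance values, and 20 simulations of unchanged groups gave mean correlations of 0.515, 0.513 and 0.516. The covariances were 0.209, 0.320 and 0.216, against simulated ones of 0.0112, 0.0111 and 0.0111. At 1 h and 3 h, 889 genes rose and 861 fell at both times, where independent lists would share 361 and 322. The counts were 1130 and 1069 at 3 h and 6 h (487 and 397 for independent lists), and 900 and 931 at 1 h and 6 h (454 and 379). Opposite calls numbered 133, 60 and 206 for these 3 pairs of times. In the simulations 0 genes were called in the same direction at both times of any pair. As no gene differed in them, almost none could be called, so this 0 does not bear on the shared counts above. The covariances argue against independent noise in the shared controls as the main source of the covariance between times. The simulations held no deviation common to many genes, such as that of 0 h replicate 3. The 3 control libraries are too few to split, so part of the covariance and of the shared calls may still come from the shared controls.

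Between 1 h and 3 h, the phosphate genes PHO5 and PHO84 rose, and the mating genes AGA2 and BAR1 fell. PHO5 stood at 305 ± 6.20 CPM at 3 h against 13.1 ± 0.405 at 1 h (mean ± SD, n = 3), a log2 fold change of 4.54 ± 0.08 (SE, adjusted p = 4.0e-13), and PHO84 at 303 ± 23.0 against 25.7 ± 0.651 (3.56 ± 0.17). AGA2, the binding subunit of a-agglutinin (YGL032C, chromosome VII, 436570 to 436833, minus strand), stood at 21.8 ± 1.08 CPM against 93.5 ± 2.11 (-2.10 ± 0.08, adjusted p = 1.5e-09), and BAR1, the protease that degrades alpha-factor, at 70.5 ± 4.12 against 292 ± 16.7 (-2.05 ± 0.10). PHO89 (4.44 ± 0.46) and HES1 (3.29 ± 0.12) rose, and PRM1, a membrane fusion protein of mating (-2.03 ± 0.13), and the argininosuccinate synthase ARG1 (-1.96 ± 0.17) fell.

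Phosphate genes rose in 16 of 18 cases between 1 h and 3 h with 0 lower (17 adjusted over the list alone; median 1.01, adjusted p = 2.92e-13, adjusted p = 9.78e-04 with an estimated correlation). Iron regulon genes rose in 16 of 29 cases and fell in 1 (18 and 1 adjusted over the list alone; median 0.32, adjusted p = 3.74e-07, adjusted p = 0.00461 with an estimated correlation). FIT2 was at 2.88 ± 0.06. Hypoxic genes rose in 12 of 20 cases and fell in 2, also adjusted over the list alone (median 0.47, adjusted p = 1.91e-05, adjusted p = 0.0117 with an estimated correlation). All 7 a-specific genes fell, also adjusted over the list alone (median -1.72, adjusted p = 1.3e-08, adjusted p = 0.0215 with an estimated correlation). Drug resistance genes fell in 8 of 13 cases and retrograde response genes in 6 of 9, with 0 higher and the same counts adjusted over the list alone (medians -0.48 and -0.58, adjusted p = 1.76e-04 and 9.12e-05, adjusted p = 0.0405 and 0.0207 with an estimated correlation). The ABC transporter PDR5 was at -1.22 ± 0.07. The drug resistance call with an estimated correlation ended without 0 h replicate 3 (adjusted p = 0.0847), 1 h replicate 2 (adjusted p = 0.0626), 3 h replicate 2 (adjusted p = 0.0520) or 3 h replicate 3 (adjusted p = 0.0608).

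Of 19 lists called between 1 h and 3 h, 6 kept their call with an estimated correlation. Those that lost it included the heat shock proteins (1 of 22 higher, 16 lower, also adjusted over the list alone; median -0.53, adjusted p = 2.15e-08, but adjusted p = 0.133 with an estimated correlation) and the Yap1 targets (2 of 21 higher, 12 lower, 2 and 13 adjusted over the list alone; median -0.50, adjusted p = 3.36e-05, but adjusted p = 0.111 with an estimated correlation, and 0.0454 without 0 h replicate 3). Oxidative phosphorylation genes fell in 19 of 36 cases, also adjusted over the list alone (median -0.26, adjusted p = 3.72e-05, but adjusted p = 0.299 with an estimated correlation, and 0.0287 without 0 h replicate 3), and in 12 without 1 h replicate 2. Ergosterol genes rose in 14 of 23 cases and fell in 2 (15 and 3 adjusted over the list alone; median 0.46, adjusted p = 1.05e-06, but adjusted p = 0.133 with an estimated correlation). Gcn4 targets fell in 25 of 35 cases and rose in 3 (25 and 4 adjusted over the list alone; median -0.47, adjusted p = 1.3e-08, but adjusted p = 0.133 with an estimated correlation). Histones rose in 7 of 8 cases, also adjusted over the list alone (median 0.42, adjusted p = 9.15e-05, but adjusted p = 0.133 with an estimated correlation). Ribosome biogenesis genes rose in 25 of 50 cases and fell in 1, also adjusted over the list alone (median 0.22, adjusted p = 1.67e-06, but adjusted p = 0.424 with an estimated correlation; 16 rose without 1 h replicate 2), while ribosomal protein genes fell in 80 of 138 cases and rose in 14 (86 and 17 adjusted over the list alone; median -0.24, adjusted p = 2.67e-07, but adjusted p = 0.511 with an estimated correlation). Cell wall integrity genes fell in 7 of 15 cases and rose in 1, also adjusted over the list alone (median -0.29, adjusted p = 0.0241, but adjusted p = 0.389 with an estimated correlation). This call ended without 1 h replicate 1 (adjusted p = 0.0644) or 3 h replicate 3 (adjusted p = 0.0542). V-ATPase genes fell in 6 of 23 cases (5 adjusted over the list alone; median -0.09, 0.03 with total counts, adjusted p = 0.0393, but adjusted p = 0.240 with an estimated correlation). The call ended without 3 h replicate 3 (adjusted p = 0.0854) or with the filter at 10 CPM in 3 libraries (adjusted p = 0.0542), and 3 genes fell without 3 h replicate 3 or 1 h replicate 2. Over all features 951 rose and 986 fell between 1 h and 3 h, and 49.1% of calls were higher. With total counts 1734 were higher and 552 lower, 75.9% higher.

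Between 3 h and 6 h, PBI1 and YSR3 rose, and the acid phosphatase gene PHO5 fell. PBI1 stood at 782 ± 196 CPM at 6 h against 76.5 ± 23.3 at 3 h (mean ± SD, n = 3), a log2 fold change of 3.36 ± 0.24 (SE), and YSR3, a sphingoid base phosphate phosphatase, at 212 ± 37.2 against 33.1 ± 4.99 (2.68 ± 0.15). PHO5 stood at 68.2 ± 4.31 CPM against 305 ± 6.20 (-2.16 ± 0.07). HXT5 (2.58 ± 0.21) and BTN2 (2.01 ± 0.23) rose, and SPL2 (-1.72 ± 0.14) and CYC1 (-1.49 ± 0.14) fell.

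Hypoxic genes rose in 13 of 20 cases and fell in 2, also adjusted over the list alone, and iron regulon genes rose in 17 of 29 cases and fell in 1 (18 and 1 adjusted over the list alone; medians 0.87 and 0.29, adjusted p = 4.75e-05 for both, adjusted p = 0.0192 for both with an estimated correlation). Retrograde response genes rose in 6 of 9 cases (7 adjusted over the list alone; median 0.53, adjusted p = 1.31e-04, adjusted p = 0.0226 with an estimated correlation). The isocitrate dehydrogenase subunit IDH1 was at 1.52 ± 0.05. Phosphate genes fell in 11 of 18 cases and rose in 2 (12 and 2 adjusted over the list alone; median -0.58, adjusted p = 8.16e-05, adjusted p = 0.0192 with an estimated correlation). Of 20 lists called between 3 h and 6 h, these 4 kept their call with an estimated correlation. All 4 lost it without 0 h replicate 3, a library of neither time compared (adjusted p = 0.0733 for the hypoxic list and 0.0647 for the other 3). Among the other lists, environmental stress response genes rose in 16 of 30 cases (19 adjusted over the list alone; median 1.00, adjusted p = 2.74e-06, but adjusted p = 0.382 with an estimated correlation). The cell wall protein SPI1 was at 1.98 ± 0.09. Without 0 h replicate 3 the list had 26 genes higher. Targets of the calcineurin-activated factor Crz1 rose in 12 of 15 cases and glucose-repressed genes in 13 of 22, also adjusted over the list alone (medians 0.73 and 0.83, adjusted p = 1.08e-05 and 2.22e-04, but adjusted p = 0.258 and 0.382 with an estimated correlation). Of the glucose-repressed genes 8 rose without 3 h replicate 3 and 8 without 6 h replicate 1 (median 0.51). Autophagy genes rose in 18 of 27 cases (19 adjusted over the list alone; median 0.39, adjusted p = 1.31e-04, but adjusted p = 0.299 with an estimated correlation), and in 9 without 3 h replicate 3 or 10 without 6 h replicate 1.

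Ribosome biogenesis genes fell in 41 of 50 cases between 3 h and 6 h (42 adjusted over the list alone; median -0.40, adjusted p = 5.59e-13, but adjusted p = 0.299 with an estimated correlation). Ribosomal protein genes fell in 47 of 138 cases and rose in 3, also adjusted over the list alone (median -0.14, adjusted p = 1.08e-05, but adjusted p = 0.617 with an estimated correlation). The number that fell was 27 without 3 h replicate 1, 27 without 3 h replicate 2, 31 without 3 h replicate 3 and 25 without 6 h replicate 1. V-ATPase genes fell in 13 of 23 cases and rose in 1, also adjusted over the list alone (median -0.21, adjusted p = 4.33e-04, but adjusted p = 0.0976 with an estimated correlation, and 0.0459 without 3 h replicate 3). The a-specific list was not called (4 of 7 lower, 1 higher, adjusted p = 0.0867) except without 0 h replicate 3 (5 lower, adjusted p = 0.0425, but adjusted p = 0.316 with an estimated correlation). Mitochondrially encoded genes rose in 3 of 7 cases (6 adjusted over the list alone; median 0.75, adjusted p = 0.0158, but adjusted p = 0.386 with an estimated correlation). Over all features 1177 rose and 1219 fell between 3 h and 6 h (144 and 12 by at least 2-fold), and 49.1% of calls were higher. The lists of copper-responsive, zinc-responsive, unfolded protein response and meiosis genes had adjusted camera p-values over 0.05 in all 5 comparisons with all libraries. The unfolded protein response list was called at 3 h against 0 h without 3 h replicate 3 (adjusted p = 0.0482, but adjusted p = 0.231 with an estimated correlation). Of 4 alpha-specific genes, markers of the opposite mating type, 2 passed the count filter, too few for camera. Of these STE3, the receptor for a-factor, rose at 6 h against 0 h (0.99 ± 0.18 by edgeR), between 1 h and 3 h (0.68 ± 0.19) and between 3 h and 6 h (0.54 ± 0.17). Its rise between 1 h and 3 h ended without 1 h replicate 1 (adjusted p = 0.0579) or 3 h replicate 2 (adjusted p = 0.0721). Its rise between 3 h and 6 h ended without 3 h replicate 1 (adjusted p = 0.0809), 3 h replicate 3 (adjusted p = 0.0613) or 6 h replicate 1 (adjusted p = 0.0719).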

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

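Apart from the counts of other groupings of the libraries, the tests in this part were chosen only after the results were seen, and so was the rule that singled results out. It took genes and lists called in opposite directions at consecutive times against 0 h, with the difference between those times called as well. It was narrowed after the data were seen, and other differences between times stand in the report as the consecutive comparisons.

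The a-specific mating genes had a median log2 fold change of 0.37 at 1 h and -1.33 at 3 h against 0 h, and the difference was -1.72. The call at 1 h was lost with an estimated correlation (adjusted p = 0.339) and without 0 h replicate 1, 0 h replicate 2 or 1 h replicate 3 (adjusted p = 0.0580, 0.0593 and 0.0600), and that at 3 h with an estimated correlation (adjusted p = 0.100). AGA2 went from 0.37 to -1.72, a difference of -2.10, and PRM1 from 0.66 to -1.36, a difference of -2.03. PHO5 went from -3.14 at 1 h to 1.39 at 3 h and -0.77 at 6 h, with differences of 4.54 and -2.16. The iron gene FIT1 went from -0.57 at 1 h to 1.99 at 3 h, a difference of 2.56. DAN1 went from -0.52 to 2.03, a difference of 2.55. YMR317W went from -0.80 to 1.53, a difference of 2.33.

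Replicate 3 at 0 h stood apart from replicates 1 and 2, with 172 features over 2-fold from their mean and environmental stress response genes at a median log2 difference of -1.08. Its total was 97.8% of that of the shallower of the other 0 h libraries, which argues against depth. Over the genes changed at each treated time, its median position between the other 0 h libraries (0) and that time (1) was 0.103 for 1 h, 0.0714 for 3 h and -0.0432 for 6 h, which argues against a treated library under a 0 h label. Its deviations from the group mean correlated at 0.433 to 0.450 with those of the later libraries that share its letter C in the column headers and at -0.479 to -0.431 with those of letter A, while 12 to 20 features of the later C libraries lay over 2-fold from the other 2. A factor shared by the C libraries and a difference in the state of that culture when it was sampled stay open, as the labels do not say what the letters mark, and no biological explanation was tested, since the design names none within the 0 h group.

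Phosphate regulon genes were lower at 1 h than at 0 h and 3 h, with medians against 0 h of -0.58 at 3 h (10 of 18 lower, 4 higher; adjusted p = 0.100 with an estimated correlation) and -0.95 at 6 h. Without each of the 6 libraries of 0 h and 1 h in turn, the highest median log2 fold change at 1 h was -1.48, which argues against a single library as the cause. Over the 16 members with no near-identical copy the median was -1.38, which argues against reads shared between copies. With 0 libraries without the compound at 1 h, handling or age of the culture and exposure cannot be told apart. An effect of the compound on phosphate signalling may account for the pattern, but so may a change in the medium or handling.

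Pheromone-related and a-specific genes were, as lists, lower at 3 h than at 1 h. Of 19 pheromone response genes that are not a-specific, 11 fell and 1 rose, with a median of -0.71. Their p adjusted over the lists added after the results were seen was 2.83e-06 by camera, but 0.0682 with an estimated correlation. In the 3 h libraries the highest count of MF(ALPHA)1 or MF(ALPHA)2, transcripts abundant in alpha cells, was 3, which argues against alpha cells as the cause. However, the alpha-specific STE3 rose by edgeR (0.68, adjusted p = 0.0142, but 0.0579 without 1 h replicate 1 and 0.0721 without 3 h replicate 2). It had 41 to 71 counts in the 3 h libraries. The alpha-specific SAG1 had 162 to 232 counts in the 3 h libraries and 173 to 195 in the 1 h libraries. For diploid cells the test was 5 haploid-specific genes that pheromone does not induce, whose median was -0.15 (-0.27 to -0.02) against -1.72 (-2.10 to -0.95) in the a-specific genes, which argues against diploids as the cause, although all 9 haploid-specific genes, pheromone-induced ones included, had a median of -0.27 (5 fell; adjusted p = 0.00450 by camera, adjusted p = 0.0682 with an estimated correlation). Lower output of the pheromone response pathway is a candidate explanation: 14 other pheromone-induced genes had a median of -0.59 (camera p = 0.00632), but p = 0.150 with an estimated correlation of 0.180, so it stays a hypothesis. Time in culture cannot be separated from exposure here either.

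Counts of genes called were set against other groupings of the same libraries. For the F test over the 4 times, 1 of 100 groupings of the 12 libraries into 4 groups of 3, the real one, gave as many genes (4406). The other groupings drawn had 2601 as the highest and 0 as the median. The highest depends on the draw and was several times lower in an earlier draw. The count thus goes beyond the random groupings drawn from these libraries. Chance differences between cultures cannot be excluded, as the labels do not say that the libraries of a time came from separate cultures. In each of the 5 comparisons the 6 libraries allow 10 groupings, too few for a share under 0.05. By edgeR the real groupings called 2690 genes at 1 h, 2851 at 3 h and 3475 at 6 h against 0 h, 1937 between 1 h and 3 h and 2396 between 3 h and 6 h, and the highest of the other groupings called 0 in each. At an unadjusted p under 0.05 the other 9 groupings had at most 885, 923, 732, 180 and 320 genes in these comparisons, in the same order. All other groupings, those of the F test included, mix libraries of different times within a group. Any difference between times then adds to their spread and lowers their calls. Their counts are therefore no measure of how many genes chance alone would call. DESeq2 was not run on the groupings.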

How the results depend on the processing

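In this part, the block on the replicate letter, nuclear open reading frames only, the estimated correlation without each library and the comparisons of later times without 0 h replicate 3 were chosen only after the results were seen. Counts of called genes stayed within 1.5 times with DESeq2, DESeq2's size factors, no filter, the 10 CPM filter, features without rRNA, nuclear reading frames only, the fit of only the groups compared and each library left out. Ranges over left-out libraries were 1041 to 1317 higher and 1101 to 1649 lower at 1 h, 1108 to 1475 and 1148 to 1706 at 3 h, 1547 to 1776 and 1492 to 1826 at 6 h, 666 to 1214 and 743 to 1187 between 1 h and 3 h, 854 to 1406 and 930 to 1452 between 3 h and 6 h, and 4109 to 4730 for the F test. The highest of most ranges were without 0 h replicate 3. Lists that were not called with all libraries, gained a call without 1 library and are not named for it in the report were cell wall integrity at 1 h (without 0 h replicate 1, 0 h replicate 2 or 1 h replicate 3, adjusted p = 0.0361, 0.0445 and 0.0390), nitrogen catabolite repressed genes at 1 h (0 h replicate 2, adjusted p = 0.0445; also with the 10 CPM filter, adjusted p = 0.0226, where the median was 0.50 against 0.10), hypoxic genes at 3 h (3 h replicate 3, adjusted p = 0.0482) and glucose-repressed genes at 6 h (0 h replicate 1, 0 h replicate 2 or 6 h replicate 3, adjusted p = 0.0238, 0.0187 and 0.0380). With an estimated correlation the adjusted p was 0.165 to 0.569 in these left-out fits. Counts of 601 features were too low to test, among them most of the 299 tRNAs, of which 16 were tested. Effects of depth on the other features were not tested.

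Total counts alone moved the counts of genes most in the comparisons with 0 h and between 1 h and 3 h, and leaving out a library did between 3 h and 6 h. The estimated correlation moved the counts of lists most. At 1 h against 0 h 2575 genes were higher and 602 lower (229 and 99 by at least 2-fold), at 3 h 3576 and 498 (378 and 101), at 6 h 3278 and 809 (659 and 172), and between 1 h and 3 h 1734 and 552. The shift follows from leaving out TMM factors that differ between 0 h and later times. PDR3, a regulator of drug resistance, went from -0.32 at 3 h against 0 h to 0.012, and was the only named gene that changed direction under any setting run. Of 32 lists, camera called 15 at 1 h, 16 at 3 h, 20 at 6 h, 19 between 1 h and 3 h and 20 between 3 h and 6 h, and with an estimated correlation 3, 1, 2, 6 and 4. By construction that setting allows for genes of a list varying together, including any variation shared by libraries of a replicate letter. Fry, which does not compare a list with other genes, called 23 at 1 h and 31 at 6 h against 0 h.

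The correlation of fold changes between 3 h and 6 h was 0.833 over genes called by the F test and 0.834 over genes with a mean of at least 10 CPM, and that between 1 h and 6 h was 0.617 over the latter. The cause was not tested. Leaving out a 0 h library gave 0.734 to 0.758 for 1 h and 3 h, 0.587 to 0.607 for 1 h and 6 h, and 0.818 to 0.836 for 3 h and 6 h.

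The column headers carry replicate letters A, B and C. Deviations from the group mean of libraries with the same letter correlated at 0.238 to 0.461 for A, -0.0769 to 0.0723 for B and 0.268 to 0.450 for C, and 9 of 12 libraries matched their own letter best. Libraries with letters A and C thus deviated together across times and those with B did not. The letters were not taken as pairs because the pairs of B did not reach 0.1. The values of B do not decide whether the letters pair the libraries. Deviations from a group mean cancel out, and those of A and C within a time correlated at -0.856 to -0.698. A B library between them would therefore share little deviation with other B libraries, paired or not. On the second principal component the libraries stood in the order A, B, C at each time. Every p with an estimated correlation in this report comes from a fit without a block on the letter. Deviations shared by libraries of a letter thus stayed in the spread from which that correlation was estimated. The list tests with the block below used the preset correlation only. With the letter as a replicate block 1572 genes were higher and 1477 lower at 1 h, 1658 and 1503 at 3 h and 2039 and 1718 at 6 h, cell wall integrity and glucose-repressed genes at 1 h gained a list call (adjusted p = 0.0450 for both), heat shock proteins at 6 h lost theirs (adjusted p = 0.0508), no other list or named gene changed its call, and no count moved by 1.5 times.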

Other observations

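All tests and lists in this part were chosen only after the results were seen, so they describe these libraries and are no independent evidence. Camera p-values here are adjusted over the added lists alone. Genes of proteasome subunits, the protein-degrading complex, rose in 25 of 33 cases at 1 h against 0 h (27 adjusted over the list alone; median 0.22, adjusted p = 6.28e-06 by camera, but adjusted p = 0.384 with an estimated correlation), and in 15 cases without 0 h replicate 3. Between 1 h and 3 h 32 of 33 fell (median -0.45, adjusted p = 1.04e-17, but adjusted p = 0.0682 with an estimated correlation), with a median of -0.33 under total counts. At 3 h against 0 h the median was -0.23, and 0.11 with total counts. All 11 genes of branched-chain amino acid synthesis fell at 1, 3 and 6 h against 0 h, with medians of -0.53, -1.12 and -1.55 (adjusted p = 0.384, 0.180 and 0.141 with an estimated correlation). With total counts 6, 10 and 11 of them fell. Of 13 genes of adenine synthesis 11 fell at each of these times, with medians of -0.79, -1.03 and -1.10 (adjusted p = 0.384, 0.311 and 0.247 with an estimated correlation), and 1 rose at 1 h. Both lists had negative medians under each scaling and without 0 h replicate 3.

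The 3 genes of aromatic amino acid breakdown controlled by Aro80 rose at 1, 3 and 6 h against 0 h by edgeR, with medians of 2.27, 1.82 and 1.73, and 3 genes are too few for camera. Of 24 seripauperin (PAU) genes, a family of cell wall proteins whose members share reads, 7 passed the count filter. At 6 h against 0 h all 7 rose (median 2.36, adjusted p = 0.00140, but adjusted p = 0.141 with an estimated correlation). Members low at 0 h can pass the filter through 6 h alone, so this rise may be partly selected. As members share reads, the 7 are not separate evidence, which the preset correlation does not allow for. Of 299 tRNA genes 16 passed the count filter. Of these, 9 rose and 1 fell at 1 h, 7 rose at 3 h and 11 rose at 6 h against 0 h by edgeR. The median log2 fold changes were 1.42, 1.19 and 1.18, while tRNAs took under 0.01% of counts in any library. Genes low at 0 h can pass the filter through later times alone, so these rises are partly selected and uncertain. Of 74 snoRNA or snRNA genes 4 rose and 39 fell at 3 h against 0 h, 20 rose and 0 fell between 3 h and 6 h, and 8 rose and 5 fell at 6 h against 0 h by edgeR. Their median log2 fold change at 3 h against 0 h was -0.49 with TMM scaling. The share of all snoRNAs and snRNAs in the counts was 5.89% ± 0.348 (SD, n = 3) at 0 h and 5.47% ± 0.541 at 3 h. Part of the fall at 3 h may thus depend on the scaling.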
